A study of Homo sapiens with 4 samples.

How the data were processed

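Chromatin immunoprecipitation with sequencing (ChIP-seq) was carried out on HuH-7 cells, an established human hepatoma line. The antibodies were raised against acetylated lysine 27 of histone H3 (H3K27Ac), trimethylated lysine 4 of histone H3 (H3K4me3) and RNA polymerase II (RNApol II). Each antibody gave 1 library, and input DNA gave 1 more, so there were 4 libraries and no replicates. Groups were taken from the antibody in the labels, and the input library was identified by its title. The deposited files used here were 3 peak lists, 1 per antibody. Input DNA entered through the peak caller, and its own signal was not analysed here. Per the submitters' processing notes, reads were aligned with Bowtie2 to the hg38 build. The Bowtie2 version, the trimming and the mapping quality filter were not given in the sources used here.

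Per the file headers, peaks were called with MACS 1.4.0rc2 on each library separately, against the same input library. The p cutoff was 0.05, the fragment size d was 200 bp, at most 2 tags were kept at any position, and the smaller of both data sets was scaled towards the larger. The p cutoff is permissive and the lists hold many weak peaks. The tag count of each peak in the deposited files is the number of tags of that library in the peak. The fold enrichment ratio is named but not defined in the deposited files. It was read by the known definition of this caller, as the tags at the summit over the local background expected from the input. The deposited score of each peak is 10 times the negative log10 of the p-value of the caller. The deposited FDR is a percent that this caller is known to derive by swapping ChIP and input. All these values belong to single peaks and are the authors'. They were used only to describe, rank or filter peaks within a list, and folds are not comparable between lists. Starts and ends are 1-based, as in the files.

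Per the file headers, the total tags and the tags kept after the duplicate filter were 14130253 and 2658701 for H3K27Ac, 35770328 and 33816487 for H3K4me3, 17096756 and 2844851 for RNApol II, and 25738076 and 12616725 for input. The redundant rate was 0.81, 0.05, 0.83 and 0.51 in that order. The tag size was 76 bp for H3K27Ac and RNApol II and 150 bp for H3K4me3. Depth, tag size and antibody therefore differ together between the H3K4me3 list and the other lists, and numbers and widths of peaks cannot be compared as properties of the marks alone. A missing H3K27Ac or RNApol II peak is weaker evidence than a missing H3K4me3 peak.

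Genes were taken from a RefSeq table of assembly GRCh38.p14, the same coordinate system as hg38, with 59661 genes on chromosomes 1 to 22, X and Y, of which 20033 are protein-coding. The table gives the start and end of each gene but neither strand, transcript starts nor exons, and no genome sequence was used. The design had named windows around transcription start sites. In their place, a gene was counted as carrying a mark when a peak overlapped the window within 1 kb of either end of the gene. This adds RNApol II and other signal at 3' ends and misses internal start sites. The number of RefSeq transcripts (1, 2 to 3, or 4 and more) replaced the number of start sites in the matching of random gene lists. Peaks were classed as within 1 kb of an end of any gene, inside a gene by their midpoint, or outside genes, and exons and introns were not separated.

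Overlap meant at least 1 shared bp. The background was the share found after 200 circular shifts of the second list along each chromosome, with the largest coordinate seen in the files or the gene table as the chromosome length. Shifted peaks can fall into assembly gaps, so shifts of 100 kb to 1 Mb were added after the data were seen. Intervals are Wilson 95% intervals of a share, which cover counting error only, because tags are not independent molecules and no library was repeated. No p-value was computed across peaks or genes. All 3 lists share the input library, so part of their overlap may come from it, and the input could not be split.

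There were 18 gene lists, fixed before the data were examined. They are hepatocyte transcription factors, secreted plasma proteins, complement, oncofetal and liver cancer genes, bile acid synthesis and transport, cholesterol synthesis and uptake, drug metabolism, urea cycle with gluconeogenesis and amino acid breakdown, hepatitis virus entry factors, housekeeping, cell cycle, neuronal, blood cell and skeletal muscle markers, other liver cell types, HOX genes, cytosolic ribosomal protein genes and replication-dependent histone genes. All but 1 of the listed genes were found among the protein-coding genes, the exception being the noncoding H19. A list's count was set against 10000 random lists of protein-coding genes matched on the number of transcripts. It was called above or below them when fewer than 2.5% of random lists were as high or as low. With 72 such percentiles, about 3.6 would lie outside by chance. Neighbouring members of a list can share peaks, which random lists of scattered genes do not allow for. H3K27Ac peaks over 2.5 kb from every gene end were called distal and counted within 50 kb of either end of each gene. Domains were made by joining H3K27Ac peaks under 12.5 kb apart or H3K4me3 peaks under 1 kb apart, and ranked by the length covered by peaks. Spearman correlations of folds across genes used the strongest peak at the gene ends. Those of widths used the total width of all peaks at the gene end where that total was larger. Genes are not independent replicates. The covered share of a gene is the percent of its length under RNApol II peaks.

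Genes were named by a rule set before the data were examined. It takes up to 4 members of each list with all 3 marks and the widest total H3K27Ac peaks, and up to 4 members with none in alphabetical order. It also takes the 10 genes with the widest H3K4me3 and H3K27Ac domains at a gene end, the 5 genes with RNApol II alone and the highest fold, and ALB, AFP, APOA1, APOB, SERPINA1, HNF4A, FOXA2, MYC, GAPDH and ACTB. Some genes that this rule takes are not reported here. Other genes that are named were chosen after their values were seen, among them members of the HOX list, SLC10A1, noncoding genes, and genes named for RNApol II cover.

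The list test was checked on simulated data. Of 400 simulated lists of 25 genes drawn with 4 times the odds of a marked gene, 77.25% were called high, and 1.75% of lists drawn without that preference were called. Computation used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9. Alternatives were the stronger part of each list, lists of equal length, windows of 500 bp and 2.5 kb, other overlap rules and backgrounds, other distances and stitching, and other matching. A fold of at least 5 (for all results other than the number, width and covered length of peaks) and an FDR of at most 5% were added after the data were seen. So were shifts of 100 kb to 1 Mb, matching on gene length and the use of only the gene end with the strongest H3K4me3 peak.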

Results

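HuH-7 cells, a human liver cancer line, were profiled by ChIP-seq for H3K4me3, a mark of gene starts, H3K27Ac, a mark of active promoters and enhancers, and RNA polymerase II (RNApol II), the enzyme that transcribes protein-coding genes. The series set out to examine where these 3 marks lie in this line. There was 1 library per antibody and 1 input library, so no value below has a replicate error, and intervals cover counting error only. The caller kept 33816487 tags for H3K4me3, 2658701 for H3K27Ac, 2844851 for RNApol II and 12616725 for input. Coordinates are hg38.

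The first question was how much of the genome each list covers. The H3K4me3 list had 54376 peaks with a median width of 1692 bp that covered 119 Mb. The H3K27Ac list had 87771 peaks with a median width of 579 bp that covered 81.4 Mb, and the RNApol II list had 95020 peaks with a median width of 551 bp that covered 77.8 Mb. Many peaks of both less deeply kept libraries were weak. Peaks of only 3 tags made up 33.3% of the H3K27Ac list and 39.8% of the RNApol II list, whereas no H3K4me3 peak had fewer than 12 tags. A fold of at least 5 over the input was reached by 27.1% of H3K27Ac, 66.8% of H3K4me3 and 24.7% of RNApol II peaks. The FDR of the caller was 100% for 44.5% of the H3K4me3 peaks and never below 4.79% in that list. An FDR of at most 5% was met by 97.1% of H3K27Ac and 95.7% of RNApol II peaks but 23.8% of H3K4me3 peaks. This filter therefore shortens mainly the H3K4me3 list.

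The marks lay together far more often than shifted lists did. Of the H3K4me3 peaks, 63.6% (95% interval 63.2 to 64.0) overlapped an H3K27Ac peak, against a mean of 7.73% after circular shifts, and 50.3% (49.8 to 50.7) overlapped RNApol II, against 7.94%. Of the H3K27Ac peaks, 51.8% overlapped H3K4me3, against 5.73% after shifts (19.05% with an FDR of at most 5% and 72.2% at a fold of at least 5), and 39.1% (38.7 to 39.4) overlapped RNApol II, against 5.12%. Of the RNApol II peaks, 42.5% overlapped H3K4me3 and 37.4% overlapped H3K27Ac, against 5.76% and 4.91%. The share with H3K4me3 was 23.8% at an FDR of at most 5% and 74.0% at a fold of at least 5, so the order of the overlaps depended on the filter. Each observed share was above all 200 shifts. All lists were called against the same input, so part of this excess may come from the input.

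**Figure D1:**
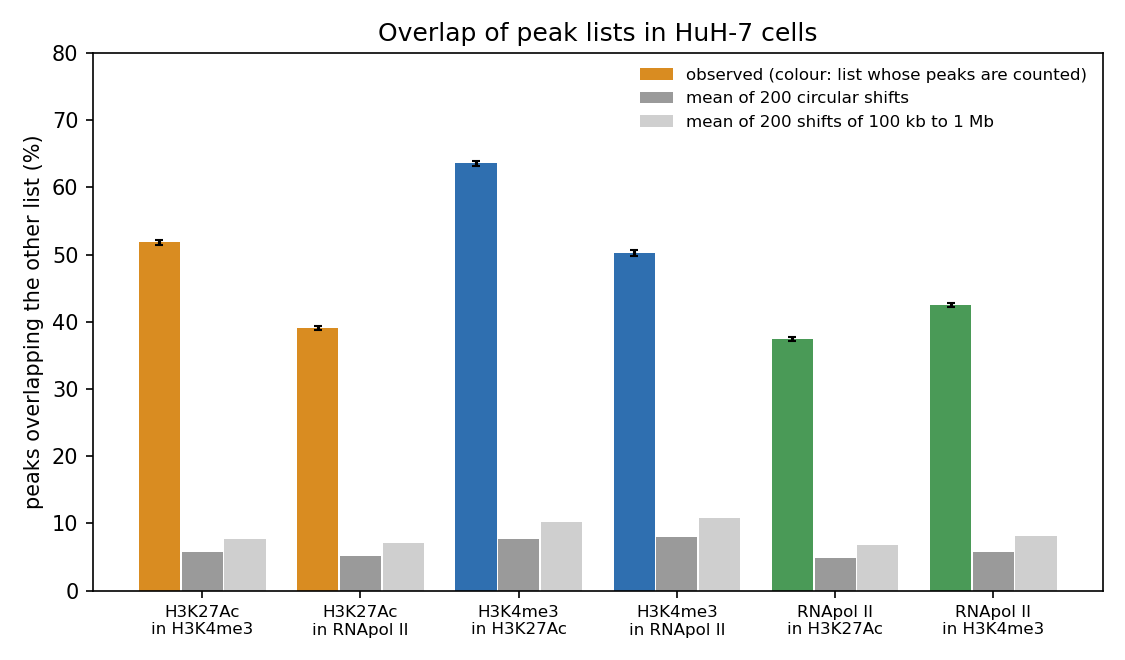
Percent of the peaks of 1 list (first name, bar colour) that overlap a peak of the other list, with Wilson 95% intervals, beside the mean of 200 circular shifts (dark grey) and of 200 shifts of 100 kb to 1 Mb (light grey). The observed shares lie between 37.4% and 63.6%, and the shifted means between 4.91% and 10.8%.

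Peaks that overlapped both other lists were the strongest of each list. The 21282 H3K4me3 peaks that overlapped both H3K27Ac and RNApol II had a median fold of 36.8 and a median width of 2847 bp. The 13755 H3K4me3 peaks that overlapped neither had a median fold of 4.75 and a median width of 1097 bp. The 25828 H3K27Ac peaks that overlapped both had a median fold of 6.11 and 16 tags, against 2.17 and 3 tags for the 33831 that overlapped neither. A different picture was found for the 8466 H3K27Ac peaks that overlapped RNApol II alone. They were narrow, with a median of 375 bp, and had a median fold of 1.91 with 10 tags.

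Relative to genes, all 3 marks lay at gene ends more often than after shifts. Of the H3K4me3 peaks, 34.6% lay within 1 kb of the end of an annotated gene, against 11.99% after circular shifts, and 85.5% of those with an FDR of at most 5% did. The shares were 29.0% for RNApol II, against 8.95%, and 21.4% for H3K27Ac, against 8.75%, and they were 61.3% and 38.6% at a fold of at least 5. The order of H3K4me3 and RNApol II depended on the lists and the window, and RNApol II was ahead with lists of equal length, 38.6% against 34.6%. H3K4me3 peaks at gene ends had a median fold of 46.6 and a median width of 2759 bp, while those inside genes had 5.13 and 1473 bp. Outside genes lay 25.4% of H3K27Ac, 24.5% of H3K4me3 and 23.5% of RNApol II peaks, all below the means of 41.0%, 39.7% and 40.7% after shifts.

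Of the 20033 protein-coding genes, 10531 (52.6%, 51.9 to 53.3) had all 3 marks within 1 kb of a gene end and 4684 (23.4%) had none. Peaks of a gene, and the folds given below, can come from different ends. Examples are HNF4A, SERPINA1, E2F1, SPINK1, ALB, AFP, OCLN, CLDN1, LYZ, CD68 and PC. At the end with the strongest H3K4me3, 10096 genes had all 3 marks. H3K4me3 was at 14447 genes, RNApol II at 13547 and H3K27Ac at 11078. Of the genes with H3K27Ac, 97.4% also had H3K4me3 and 288 did not, a number that was 1132 at an FDR of at most 5% and 94 at a fold of at least 5. RNApol II was at 97.6% (97.3 to 97.9) of the genes with both histone marks, at 62.6% (61.0 to 64.2) of those with H3K4me3 and no H3K27Ac, and at 13.0% (12.1 to 13.9) of those without H3K4me3. The median H3K4me3 fold was 74.5 at genes with all 3 marks, 43.6 at the 2290 genes with H3K4me3 and RNApol II alone, and 12.47 at the 1367 genes with H3K4me3 alone. These counts depended on the filter, with 4248 and 2229 genes at a fold of at least 5 and 1440 and 194 at an FDR of at most 5%. The class of H3K4me3 with H3K27Ac and no RNApol II held only 259 genes.

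The table of genes gives no strand, so the gene end that carried H3K4me3 was used to tell the ends apart. Among genes of at least 5 kb, 11171 had H3K4me3 at just 1 end. RNApol II was at that end in 86.4% of them and at the other end in 30.2%, and H3K27Ac in 72.4% and 5.998%. RNApol II at the other end alone was found in 1.44%. RNApol II therefore lay at the end without H3K4me3 5 times as often as H3K27Ac, mostly in genes that had it at both ends.

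Housekeeping and growth genes were the most completely marked. All 22 cell cycle genes had all 3 marks, among them MYC, which drives proliferation, with folds of 82.81 for H3K4me3, 4 for H3K27Ac and 46.67 for RNApol II, and the cyclin gene CCND1, with 63.76, 17.61 and 104.69. E2F1, a regulator of S phase entry, had an RNApol II fold of 30, and MCM5, a part of the replicative helicase, had 7.45. CCND1 was covered by RNApol II peaks over 99.3% of its length. All 3 marks were at 19 of 20 housekeeping genes, including GAPDH (H3K4me3 95.7, H3K27Ac 16.5, RNApol II 92.78) ACTB (100.75, 44.25 and 106.4) and EEF1A1 (68.09, 21.72 and 54.62). They were also at 77 of 79 cytosolic ribosomal protein genes, such as RPS12, where RNApol II reached a fold of 172.13, RPL23A (60.23), RPS9 (53.75) and RPL41 (70.83). The exceptions, without any mark, were 2 genes on chromosome Y. Of the replication-dependent histone genes, 63 of 69 had all 3 marks, with a median RNApol II fold of 101.92. H2AC6, H2BC7 and the neighbours H2AC13 and H2BC13 had the widest H3K27Ac, whereas H1-6, H2AC1, H2BC1 and H4C6 were among the 6 with none. In each of these 4 lists, none of the 10000 random lists had as many genes with all 3 marks. Neighbouring histone genes share peaks, so their members are not independent.

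Hepatocyte transcription factors, secreted plasma proteins and complement genes were marked more often than random lists as well. Of 25 hepatocyte transcription factors, 21 had all 3 marks, against a mean of 54.8% in random lists, of which 0.23% had as many. CEBPA had an RNApol II fold of 213.57 and was covered by RNApol II peaks over its whole length, 100%, as were CEBPB and FOXA2. HNF4A had folds of 75.15 for H3K4me3, 12.21 for H3K27Ac and 10 for RNApol II, and FOXA2 had 135.51, 6.67 and 22.73. The bile acid receptor gene NR1H4 and its target NR0B2 had H3K27Ac folds of 34.28 and 41.67. Of 32 genes of secreted plasma proteins, 26 had all 3 marks, and 0.03% of random lists had as many. APOB, the structural protein of low-density lipoprotein, had folds of 125.25 for H3K4me3, 110.94 for H3K27Ac and 196.77 for RNApol II. APOA1 had 40.66, 25.61 and 26.39, and APOA2 had 73.31, 54.76 and 58.54. H3K27Ac folds were 53.57 at ITIH2, 48.84 at APOC3 and 34.52 at AMBP. SERPINA1, which encodes alpha-1 antitrypsin, had strong H3K4me3 and RNApol II peaks at opposite ends, with folds of 64.11 and 23.47. The highest H3K27Ac fold at its ends was 3.12, in a peak of 3 tags. ITIH4 had no mark. All 3 marks were at 16 of 20 complement genes, and 0.72% of random lists had as many. Among those 16, MBL2 (H3K27Ac fold 55.17), C8A (39.39), MASP1 (13.46) and SERPING1 (9.75) had the widest H3K27Ac, and C6 had no mark. The complement and plasma protein calls depended on the filter, and that of complement was also lost among the stronger 50% of peaks, with 13 genes. At an FDR of at most 5%, 8 complement and 17 plasma protein genes had all 3 marks, neither outside random lists.

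Metabolic lists differed from each other. Cholesterol synthesis and uptake had all 3 marks at 17 of 19 genes, and 0.20% of random lists had as many. Among those with the widest H3K27Ac were HMGCS1, an enzyme of cholesterol synthesis (H3K4me3 116.99, H3K27Ac 18, RNApol II 55.56), and SREBF2, a regulator of the pathway (103.59, 19 and 44.17). In bile acid synthesis and transport, 7 of 14 genes had all 3 marks, close to the mean of 49.9% of random lists. Among those 7, ABCC2, ABCG5, SLCO1B3 and CYP27A1 had the widest H3K27Ac, with folds of 9.82, 22.64, 18.55 and 6.52. The H3K4me3 peak of ABCG5 was weak, with a fold of 4.75 and an FDR of 100%. CYP7A1 and CYP8B1, enzymes of bile acid synthesis, had no mark. In drug metabolism, 7 of 25 genes had all 3 marks, against a random mean of 46.9%, and 4.27% of random lists had as few, which is within the limits. ALDH1A1, CYP1A1, CYP3A5 and SULT2A1 had all 3 marks, and CYP1A2, CYP2A6, CYP2B6 and CYP2C8 were among the 9 with none. Of 16 genes of the urea cycle, gluconeogenesis and amino acid breakdown, 10 had all 3 marks, within the limits. ARG1 of the urea cycle had folds of 11.87, 14.49 and 2.88 for H3K4me3, H3K27Ac and RNApol II, and PC, an enzyme of gluconeogenesis, had 43.77, 7.65 and 34.7. HGD and TAT, which break down tyrosine, had H3K27Ac folds of 15.67 and 14.09. The strongest peaks of TAT, like those of ABCG5, all lay at the lower-coordinate end of the gene. Without strand it is not known whether this is the start of either gene. G6PC1 and PCK1, also enzymes of gluconeogenesis, and GYS2, liver glycogen synthase, had no mark.

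Oncofetal and liver cancer genes had all 3 marks at 12 of 15 genes, and 4.58% of random lists had as many, which is within the limits. H3K27Ac, with or without the other marks, was at 13 of 15, above random lists (1.93%), a call lost with lists of equal length, within 2.5 kb and at a fold of at least 5. AFP, the fetal counterpart of albumin, had folds of 26.58 for H3K4me3, 37 for H3K27Ac and 14.44 for RNApol II. IGF2BP1 had 83.68, 34 and 27, IGF2BP3 had 55.03, 24.65 and 18.92, and SPINK1 had 48.04, 19.49 and 12.77. Of 9 hepatitis virus entry factors, 7 had all 3 marks, within the limits. CLDN1 (H3K4me3 116.64, H3K27Ac 53, RNApol II 34.81) and OCLN (72.72, 20 and 25) take part in the entry of hepatitis C virus, and so does EPHA2 (141.28, 9.18 and 46). SLC10A1, the receptor of hepatitis B virus, had neither histone mark at its ends, and its RNApol II peak had a fold of 10.23.

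**Figure D2:**
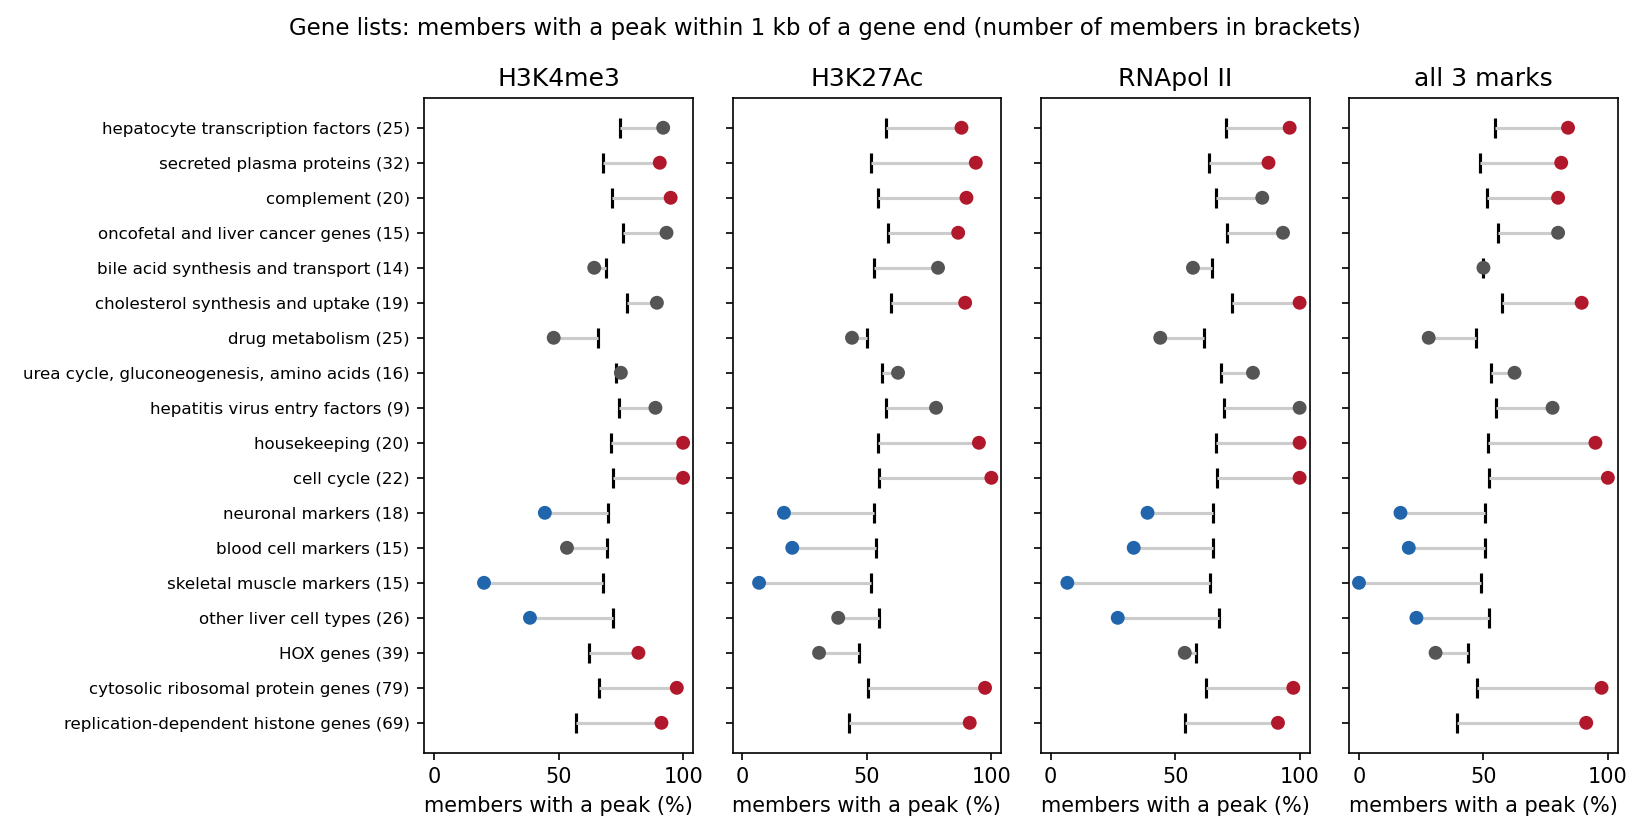
Percent of the members of each gene list with a peak within 1 kb of a gene end (points), for each mark and for all 3 together, joined to the mean of 10000 random lists matched on the number of transcripts (vertical ticks). Red points had fewer than 2.5% of random lists as high, blue points had fewer than 2.5% as low, and grey points neither. All 22 cell cycle genes and none of the 15 skeletal muscle markers had all 3 marks.

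Markers of other tissues were marked less often than random lists. None of 15 skeletal muscle markers had all 3 marks, and DES, MB, MYF5 and MYF6 were among 10 with none. Of 18 neuronal markers, 3 had all 3 marks, and 0.27% of random lists had as few. These were TUBB3, with an RNApol II fold of 122.31, SNAP25 and SYT1, the last pair with H3K27Ac peaks of 5 and 3 tags. GAD1, GAD2, GRIN2B and NEFL were among the 9 neuronal genes with none. Of 15 blood cell markers, 3 (LYZ, CD3E and CD14) had all 3 marks, and 1.42% of random lists had as few. CD2, GATA1 and HBB were among the 7 with none. The H3K27Ac peak of CD14 had only 3 tags. At LYZ the strongest RNApol II peak lay at the opposite end from the strongest histone peaks. The strongest peaks of CD3E all lay at its higher-coordinate end, and without strand it is not known whether this is its start. The blood call was lost with lists of equal length, and at a fold of at least 5, where 2 genes had all 3 marks. Markers of other liver cell types had all 3 marks at 6 of 26 genes, and 0.27% of random lists had as few. The biliary genes SOX9 and KRT19 were among them, with RNApol II folds of 40.71 and 78, and so were PECAM1 (4.44) and CD68 (35.83). The strongest histone peaks of CD68 started at 7582706 or beyond, outside the gene, which ends at 7582111. Its strongest RNApol II peak lay at the other end. Whether these histone peaks belong to a neighbouring gene was not tested. The endothelial genes CDH5 and CLEC4G and the macrophage genes CD163 and CD5L had no mark.

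HOX genes, which set position along the body axis, differed between their 4 clusters. H3K4me3 was at 32 of 39 HOX genes, above random lists (0.50% as high), whereas H3K27Ac was at 12, within the limits (2.73% as low). In HOXC, 9 of 9 genes had H3K4me3 and 8 had H3K27Ac, with HOXC4, HOXC5, HOXC6 and HOXC11 as those with the widest H3K27Ac. In HOXA, 11 of 11 genes had H3K4me3 and RNApol II, and 4 had H3K27Ac. In HOXD, 8 of 9 genes had H3K4me3, 1 had RNApol II and none had H3K27Ac. In HOXB, 4 of 10 genes had H3K4me3 and none had H3K27Ac, and HOXB1, HOXB2, HOXB3 and HOXB4 were among the 6 without any mark. HOX genes of a cluster share peaks, and the H3K27Ac library kept far fewer tags than the H3K4me3 library, so a missing H3K27Ac peak is weaker evidence than a missing H3K4me3 peak. The H3K4me3 call was lost among the stronger peaks, without matching, and at an FDR of at most 5%, where 20 genes had H3K4me3.

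Away from gene ends, 61803 H3K27Ac peaks (70.4%) lay over 2.5 kb from the end of every gene. RNApol II overlapped 26.99% (26.6 to 27.3) of these distal peaks, against 4.76% after shifts, and 67.8% of the H3K27Ac peaks nearer to a gene end. H3K4me3 overlapped 42.2% of the distal peaks, against 5.47%. The H3K4me3 overlap depended on the filter. It was 4.85% at an FDR of at most 5%, close to the lowest FDR of that list, against 2.08% after shifts, and 58.6% at a fold of at least 5, against 5.36%. Distal H3K27Ac was dense around several lists of liver genes, while bile acid genes, with 4.79 against 3.02, stayed within the limits. Hepatocyte transcription factors had a mean of 9.48 distal peaks within 50 kb of their ends, against 3.34 in random lists, oncofetal genes had 10.2 against 3.37, hepatitis virus entry factors 12.8 against 3.44, urea cycle and related genes 6.94 against 3.18, complement 6.55 against 3.07 and secreted plasma proteins 5.97 against 2.94. At most 0.11% of random lists had as many in any of these 6. Neighbouring members, such as APOA1 and APOC3, share distal peaks, so these percentiles may look more extreme than independent genes would give. The calls of complement, of urea cycle and related genes and of plasma proteins were lost under some alternatives. Drug metabolism genes also had more, 4.56 against 2.78 (1.42% as high), although this call was lost under 5 alternatives. Housekeeping genes had 2.95 against 3.15, cell cycle genes 3.45 against 3.14 and ribosomal protein genes 2.41 against 2.82, all within the limits. So were histone genes (1.83), cholesterol genes (4.89), neuronal (2), blood (2) and muscle markers (2.20), and other liver cell types (3.35). HOX genes had fewer, 1.31 against 2.63, a call lost under 5 alternatives.

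**Figure D3:**
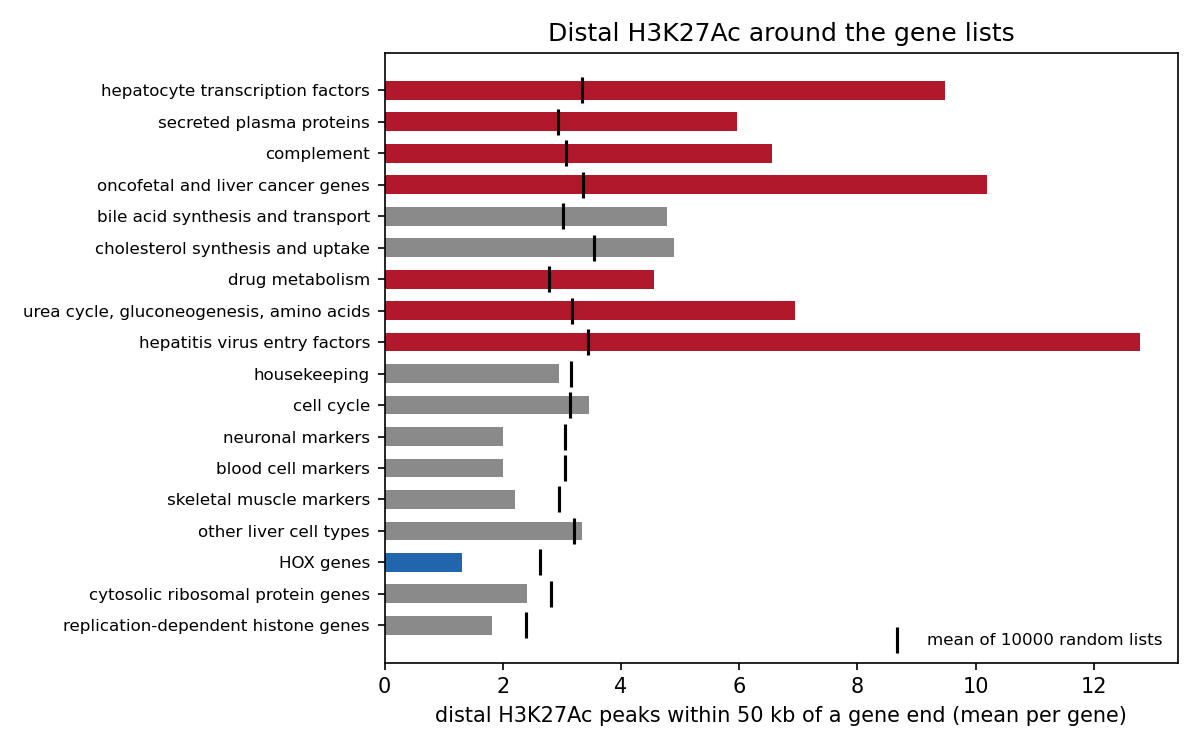
Mean number of distal H3K27Ac peaks within 50 kb of the ends of each gene, per gene list (bars), beside the mean of 10000 random lists (black ticks). Red bars had fewer than 2.5% of random lists as high, blue bars fewer than 2.5% as low, and grey bars neither. Hepatocyte transcription factors reach 9.48 and HOX genes 1.31.

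The widest H3K27Ac domains included the albumin and alpha-fetoprotein locus. Joined peaks covered 60.2 kb between positions 73374259 and 73458687 of chromosome 4, which held both ALB and AFP, and 50.8% of this domain was under RNApol II peaks. ALB had folds of 23.45 for H3K4me3, 9.82 for H3K27Ac and 9 for RNApol II, and RNApol II peaks covered 78.6% of its length. At AFP they covered 87.4%, a single H3K4me3 peak spanned 20963 bp, and a single H3K27Ac peak spanned 12536 bp. Wider H3K27Ac domains lay at COBLL1 on chromosome 2 (104.26 kb covered, joined over an end of SLC38A11 that had no peak within 1 kb), FNDC3B on chromosome 3 (95.6 kb), ADGRG6 on chromosome 6 (73.0 kb) and ZNRF3, an inhibitor of Wnt signalling, on chromosome 22 (68.9 kb). Narrower ones lay at PC and C11orf86 on chromosome 11 (58.0 kb) and EGFR, the receptor of epidermal growth factor, on chromosome 7 (55.6 kb). The PC and C11orf86 domain was made of weak peaks. The folds of its 40 peaks summed to 78.05, the lowest sum of the 20 widest domains. Those of the 43 peaks of the EGFR domain summed to 175.27. At the ends of C11orf86 the strongest H3K27Ac peak had a fold of 1.92 and the RNApol II peak a fold of 0.48. Of all 36673 H3K27Ac domains, 302 covered over 20 kb.

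**Figure D4:**
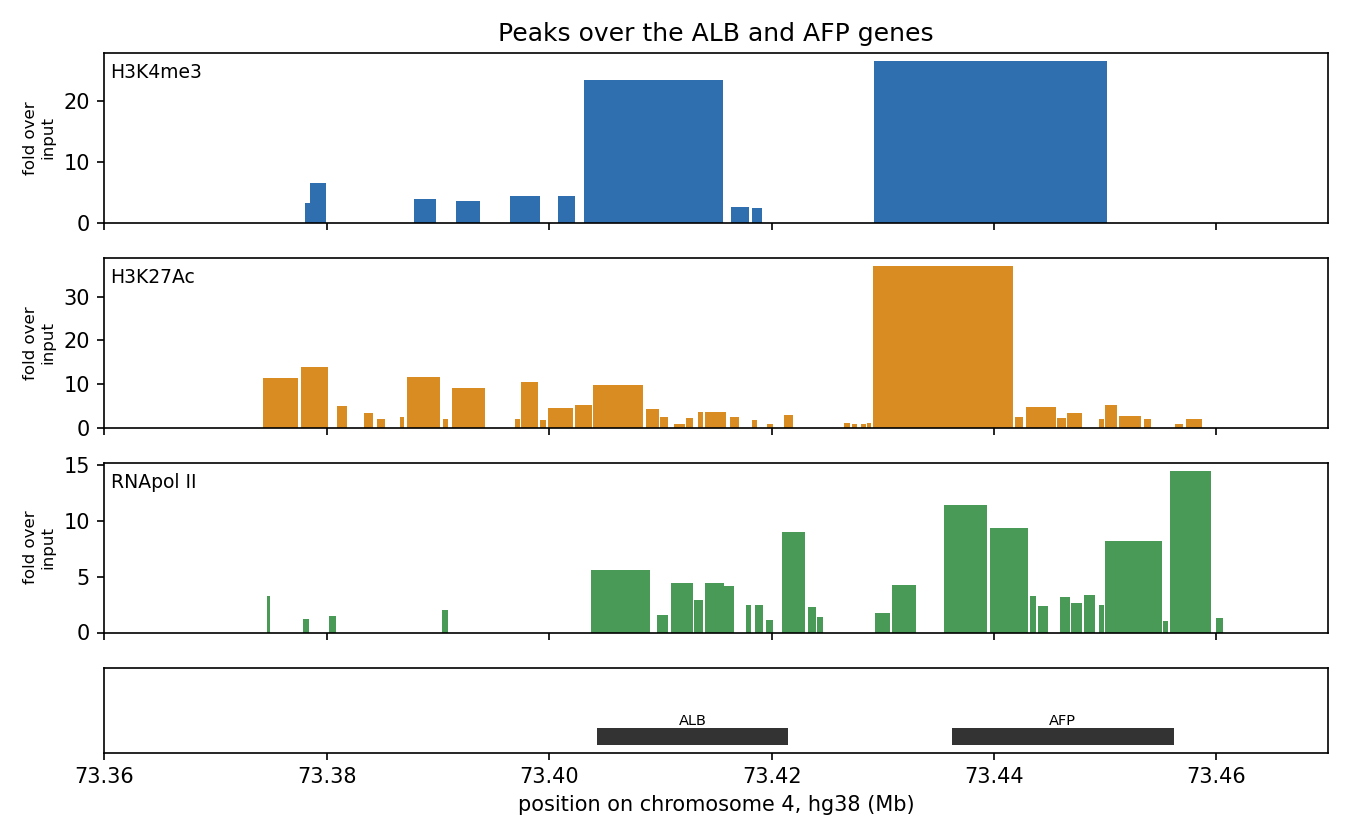
Peaks of the 3 lists over ALB and AFP on chromosome 4, each drawn from its start to its end with its fold over the input as height (separate linear axes from 0), above the gene bodies. The H3K4me3 peak of 20963 bp and the H3K27Ac peak of 12536 bp overlap at AFP.

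The widest H3K4me3 domains at protein-coding gene ends lay at RHOU (41.2 kb), CTNND1 (34.2 kb), BCL2L1 (31.6 kb), NFE2L2 (29.3 kb), SMAD7 (27.7 kb), NR2F2 (21.2 kb), AFP (20.963 kb), PARD6B (20.5 kb), RPS6KA3 (20.2 kb) and CREB3L2 (19.956 kb). BCL2L1 encodes a protein that blocks apoptosis, NFE2L2 a regulator of the oxidative stress response, and SMAD7 an inhibitor of TGF-beta signalling. H3K27Ac peaks covered 89.0% of the BCL2L1 domain, 79.3% of the SMAD7 domain and 42.5% of the NFE2L2 domain. The domain at RHOU also covered 17 genes of 5S ribosomal RNA, from position 228608293 to 228649534 of chromosome 1. RHOU starts at 228644647, so most of this domain lay outside it. Whether reads of the repeated 5S genes piled up there was not tested. Both rankings depended on the rule, and only 7 H3K27Ac and 2 H3K4me3 domains of the first 20 were shared with a ranking by the sum of folds.

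RNApol II without either histone mark was found at 614 protein-coding genes, with a median fold of 3.70. The highest folds were at ACP4 (70) and P2RY11 (69.37) on chromosome 19, IL3RA (63.51) on chromosome X, CADM4 (59.34) on chromosome 19 and NOXO1 (54.65) on chromosome 16. RNApol II peaks covered 100% of P2RY11 and 5.77% of IL3RA. The strongest peak of CADM4 ended at position 43621774, outside the gene, which starts at 43622368. Such peaks within 1 kb of a gene end may belong to a neighbouring gene, which was not tested.

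The sizes of the peaks at gene ends, by the fold of the strongest peak or by total width, rose together across genes within these libraries. Spearman's rho of the folds was 0.480 for H3K4me3 and RNApol II (12821 genes with both), 0.438 for H3K27Ac and RNApol II (10643 genes) and 0.188 for H3K4me3 and H3K27Ac (10790 genes). For the total width of all peaks at a gene end the values were 0.573, 0.524 and 0.580, so the order of the pairs depended on the measure.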

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

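The tests on small RNA and tandem repeat loci and on coinciding peak boundaries were chosen after those results were seen. For regional differences and dips of the input, the outcomes to look for were written before their tests. The shifts of 100 kb to 1 Mb used for regional differences were themselves added after the data were seen. The 3 results below concern genes outside the protein-coding comparisons and lay above all 200 circular shifts or stood apart by width. RNApol II peaks lay within 1 kb of 45.5% of the 154 snRNA genes (37.8 to 53.3), against a mean of 10.3% after shifts. H3K4me3 peaks lay within 1 kb of 80.2% of the 429 tRNA genes (76.2 to 83.7), against 8.28%, and RNApol II peaks of 53.6%. The widest H3K4me3 peak spanned 43755 bp on chromosome X, from 115845656 to 115889410, over the noncoding genes DANT1 and DANT2.

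Of the 20 RNApol II peaks with the highest folds, 13 lay at snRNA genes and 3 at snoRNA genes, led by SNORD3A on chromosome 17 (fold 730.62) and RNVU1-18 on chromosome 1 (492.59). The median fold over the input was 153 at the 70 snRNA genes with an RNApol II peak. Reads of near-identical gene copies could pile up at such loci, and the strongest H3K27Ac peaks at the same genes ranked only 5.59 percentile points below the RNApol II peaks, at a median percentile of 94.4 against 99.9, over 56 genes with both. These ranks did not decide, since the peaks ranked near the top in both lists. A pile-up shared with the input would keep the fold low, yet the fold was at least 10 at 54 of the 70 genes. This argues against such a pile-up at those 54 genes, a reading made after the folds were seen. At the others it stays open. Which copy of a family the reads came from also stays open, and no biological explanation was tested.

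The H3K4me3 peak on chromosome X lies in a tandem repeat, where reads from many copies could be placed in every library. The fold over the input at the summit was 153.0, which argues against a pile-up shared with the input at that point. This criterion was added after the fold was seen, and the fold does not describe the whole interval. The cover did not decide, since RNApol II peaks covered 56.2% of the interval, on the side of a shared signal, and H3K27Ac peaks 21.2%, between the limits for a shared and an unshared signal. The position of the signal among the repeat copies stays open, and no biological explanation was tested.

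The overlap of H3K27Ac and RNApol II was weighed because both libraries kept few tags and share the input. Regional differences such as copy number may raise overlap, but the observed share was 5.56 times the mean after shifts of 100 kb to 1 Mb and above all of them. Dips of the shared input could create weak peaks in both lists. Of H3K27Ac summits of 10 or more tags, 66.3% lay within 250 bp of an RNApol II peak. Of those of 3 tags 15.8% did, so the share was 4.21 times as high for the stronger peaks. This speaks to the stronger peaks only. Summits of 3 tags also exceeded their mean of 4.16% after circular shifts, and dips among such weak peaks were not excluded. Pile-ups at fixed places that the input shares remain a candidate explanation for a part: outside H3K4me3, 2884 of 8466 overlapping H3K27Ac peaks had both boundaries within 20 bp of those of an RNApol II peak, against 42 of 25828 inside H3K4me3, and 76.5% of the 2884 had a fold under 2. For the other 5582, of which 43.6% had a fold under 2 against 10.2% of all such peaks inside H3K4me3, pile-ups and separate signals cannot be told apart. Reads shared between both libraries, whose redundant rates were 0.81 and 0.83, could also give coinciding boundaries and were not tested, nor was a biological explanation.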

How the results depend on the processing

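The shares of overlap and of position near gene ends stayed above every shift under all settings, and no list call changed direction. The order of the marks did change. Near gene ends RNApol II passed H3K4me3 with lists of equal length (38.6% against 34.6%), within 2.5 kb (43.5% against 40.7%) and at a fold of at least 5 (61.3% against 46.2%). H3K4me3 peaks overlapped RNApol II more often than H3K27Ac among the stronger 50% (69.2% against 60.1%), at a fold of at least 5 (43.8% against 43.5%) and at an FDR of at most 5% (97.7% against 83.9%). H3K27Ac peaks overlapped RNApol II more often than H3K4me3 among the stronger 50% (48.6% against 44.6%), for summits within 500 bp (31.9% against 30.9%) and at an FDR of at most 5% (38.9% against 19.05%). RNApol II peaks overlapped H3K27Ac more often than H3K4me3 for summits within 500 bp (29.2% against 24.4%) and at an FDR of at most 5% (37.7% against 23.8%). At a fold of at least 5, H3K4me3 overlapped 72.2% of H3K27Ac and 74.0% of RNApol II peaks, and at an FDR of at most 5% 19.05% and 23.8%. Of the stronger 50% of H3K4me3 peaks 56.1% lay near gene ends, and 85.5% at an FDR of at most 5%. The cause of the changes below was not tested, except that taking part of a list lowers its peak number by construction. At an FDR of at most 5% this falls mainly on the H3K4me3 list. That filter kept 23.8% of H3K4me3 peaks, against 97.1% of H3K27Ac and 95.7% of RNApol II peaks. Fewer genes with H3K4me3 at that FDR follow from this.

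With the stronger 50% of each list there were 43885 H3K27Ac, 27188 H3K4me3 and 47510 RNApol II peaks and 27931 distal H3K27Ac peaks. The correlation of folds across genes fell to 0.127 for H3K4me3 with H3K27Ac, 0.415 for H3K4me3 with RNApol II and 0.372 for H3K27Ac with RNApol II. All 3 marks were at 13 complement genes (call lost) and 12 oncofetal genes (now above). Mean distal peaks were 2.25 for complement, 1.76 for drug metabolism and 1 for HOX (calls lost), and 0.556 for neuronal markers and 0.580 for histone genes (now below). Of the 20 widest H3K27Ac domains 10 were kept.

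At a fold of at least 5 there were 23764 H3K27Ac and 23481 RNApol II peaks and 12955 distal peaks, the correlation was 0.111, 0.367 and 0.301 in the order above, and 3 of the 20 H3K27Ac domains were kept. Virus entry factors (7) were above random lists, and the blood cell call (2) was lost, as were the distal calls of complement (0.95), drug metabolism (0.920), urea cycle and related genes (1.38) and HOX (0.718). Genes with H3K4me3 and RNApol II alone rose from 2290 to 4248 and with H3K4me3 alone from 1367 to 2229, and those with RNApol II alone fell from 614 to 262.

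At an FDR of at most 5% there were 12928 H3K4me3 peaks, the correlation of H3K4me3 was 0.159 with H3K27Ac and 0.351 with RNApol II, and 12 of the 20 H3K4me3 domains were kept. The calls of plasma proteins (17) and complement (8) were lost, and drug metabolism (3) was below. Genes with H3K27Ac and no H3K4me3, 288 as deposited, numbered 1132 here, 436 within 2.5 kb, 153 with lists of equal length and 94 at a fold of at least 5. Genes with H3K4me3 alone fell to 194 and with H3K4me3 and RNApol II alone to 1440, and those with RNApol II alone rose to 1469.

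With total widths in place of folds the correlation was 0.580, 0.573 and 0.524. Within 2.5 kb of gene ends that of folds was 0.213, 0.507 and 0.458. Within 500 bp drug metabolism (6) was below. With lists of equal length oncofetal genes (12) were above and the blood cell call (3) was lost. Without matching, drug metabolism (7) and HOX genes (12) were below, as were HOX genes (9) at the end with the strongest H3K4me3.

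For distal peaks over 1 kb from gene ends the HOX call (3.03) was lost. Over 5 kb, those of plasma proteins (3.06) and drug metabolism (2.92) were lost and histone genes (0.826) were below. Within 20 kb cholesterol genes (3.105) were above, histone genes (0.478) below, and the calls of urea cycle and related genes (2.25) and HOX (0.590) were lost. Within 100 kb that of drug metabolism (7.68) was lost. Matched on neighbouring genes, drug metabolism (4.56) lost its call and histone genes (1.83) were below. Matched on gene length, cholesterol genes (4.89) were above and HOX (1.31) lost its call.

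Stitching at 5 kb kept 8 of 20 H3K27Ac and 5 of 20 H3K4me3 domains, and ranking by the sum of folds kept 7 and 2. The most upstream start site alone and random lists matched on CpG content were not run, because strand and sequence were not used here.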

Other observations

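Noncoding genes followed several patterns, and the genes here were chosen after their values were seen. NEAT1, a nuclear RNA on chromosome 11, had folds of 61.35 for H3K4me3, 51.88 for H3K27Ac and 41.36 for RNApol II, and MALAT1, also on chromosome 11, had 48.08, 23.19 and 71.43, with RNApol II peaks over 100% of its length. H19, the noncoding member of the oncofetal list, had only an RNApol II peak within 1 kb of an end, with a fold of 3.47. That peak lay outside the gene, and RNApol II peaks covered 0% of its length. By class, 43.7% of 18303 lncRNA genes had an H3K4me3 peak in the gene or within 1 kb of it, against 26.3% after circular shifts, whereas 9.81% of 15580 pseudogenes did, against 9.36%. Of 49 rRNA genes, 63.3% had an RNApol II peak, with a median fold of 2.12, against a mean of 10.3% and a highest share of 34.7% after shifts. The 49 genes are not separate loci, since 17 of them lie together in the H3K4me3 domain at RHOU. Of 1913 miRNA genes, 27.3% had RNApol II, against 8.29% after shifts, and of 1199 snoRNA genes 25.1% did, against 7.77%.

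A hypothesis set before its test was that genes of secreted plasma proteins are covered by RNApol II peaks over more of their length than other genes. Their mean covered share was 46.3%, against 18.9% in 10000 random lists matched on gene length, none of which was as high. The same comparison put hepatocyte transcription factors (42.0% against 14.0%), housekeeping (55.6% against 19.4%), ribosomal protein (79.6% against 26.2%), histone (84.6% against 26.8%), cell cycle (39.1% against 15.4%) and cholesterol genes (28.3% against 10.5%) above all random lists. Drug metabolism genes (7.07% against 13.9%, 1.81% as low) and skeletal muscle markers (0.141% against 15.5%) lay below. Oncofetal genes (24.1%) and hepatitis virus entry factors (18.5%) lay above, and the other 7 lists within the limits. Of 16837 genes of at least 5 kb, 126 were covered over at least 90%, among them FGA of fibrinogen, the hepatocyte factor FOXA1, XBP1 and FGF19, each at 100%, and the median gene was covered over 3.48%.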
